A study of Escherichia coli BW25113 and Escherichia coli str. K-12 substr. MG1655 with 122 samples.

How the data were processed

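RNA was measured in 122 libraries of Escherichia coli K-12. Per the labels' protocols, cells were stabilised with RNAprotect and lysed with lysozyme and SDS, RNA was purified on RNeasy columns and treated with DNase, ribosomal RNA was removed with a Ribo-Zero kit for Gram-negative bacteria, and libraries were made with the KAPA Stranded RNA-Seq kit. Per the submitters' processing notes, Trim Galore, FastQC, Bowtie, featureCounts and MultiQC were used; their versions, their order and the genome build are not given in the sources used here, and neither is whether the counting used strand. Overlapping genes, antisense pairs and near-identical copies such as insertion sequences are therefore uncertain.

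The authors deposited a table of whole-number read counts per gene, which were not normalized, and a table of log2 TPM for the same genes. Both tables list 4355 genes. Back on the linear scale the deposited TPM summed to 999980 to 1e+06 per library; 350 values were at TPM 0 although the deposited count was above 0, and the lowest correlation across genes between the log2 count and the log2 TPM of a library was 0.918. Gene identifiers were locus tags. Symbols and gene neighbours came from a RefSeq gene table of assembly ASM584v2, in which 4351 identifiers matched and 4 did not, and no coordinate is printed, since the authors' build was not stated.

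Samples were grouped by strain, culture, hour and run code from their titles, giving 59 groups. The labels describe the replicates as biological duplicates. Replicates were compared before they were averaged: all 71 replicate pairs differed by more than sampling noise (chi-square per degree of freedom 1.24 to 62.4, median 9.35), so no pair looked like the same library deposited again. This does not tell separate cultures from separate library preparations, for which the labels are the only basis. Each library was counted as 1 replicate. The correlation of replicates across genes was 0.956 to 0.995. The 10 genes with the highest counts took 10.5% to 17.3% of a library. Total counts per library were 1080400 to 7934600 in PD-003, 1149300 to 8296300 in PD-004, 579920 to 10315000 in PD-005, 668830 to 4364800 in PD-006 and 966050 to 7799600 in PD-009.

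Comparisons used edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test on the deposited counts, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All libraries of a run entered one model with a coefficient per group, so that the groups of a run shared one estimate of the spread; this left 9, 11, 16, 14 and 13 residual degrees of freedom in PD-003, PD-004, PD-005, PD-006 and PD-009. Comparisons between runs used all libraries in one model. The biological coefficient of variation was 0.114 in PD-003, 0.122 in PD-004, 0.151 in PD-005, 0.109 in PD-006 and 0.174 in PD-009. In runs without a wild type, a gene was specific to a strain when it differed in the same direction from every other strain of the run; the highest of the pairwise p-values was adjusted, and the printed size is the smallest pairwise difference. For culture effects across strains, replicates were summed within strain, run and condition, and strain with run was a block. Groups with 1 library were taken to vary like the others.

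A total of 31 gene lists was tested with camera (limma 3.58.1), with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over all lists and comparisons of a family. Beside each count over all genes, a list's count adjusted over the list alone is given. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule a comparison names its deleted gene with its operon or list, up to 10 genes with the highest and up to 10 with the lowest fold change among those past the threshold, with a mean of at least 10 CPM after TMM scaling in a compared group and no overlap between the libraries, and up to 4 members of each list. Across strains the overlap condition was the same sign in every block, and for strain-specific genes there was none. Genes named outside this rule are said to have been chosen after their values were seen. A fold against a group at 0 counts is a lower bound, computed against 3 counts over the group, and covers counting error only.

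The alternatives were relative log expression scaling, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, only the libraries of the compared groups, limma on the deposited log2 TPM, fed-batch conditions only, the PD-005 wild type as the reference for runs without one, unsummed libraries or a left-out run across strains, and each library left out in turn, except the 4 that were the only one of their group (qseB batch, tnaA batch and 6 h, and baeR 18 h) and, across strains, where a run was left out instead. Leaving out the 4 libraries whose deleted gene went against the label, and leaving out the 8 PD-005 libraries under 1500000 counts, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

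The tests were tried on simulated counts with 200 changed genes drawn from the real means and library sizes. For the wild type at 6 h against batch in PD-005 (3777 genes), 19.4% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 3.85% of the calls were false. For phoB at 15 h of PD-005 the shares were 16.4%, 59.7% and 95.5%, for the baeR 18 h comparison with 1 library 2.99%, 23.9% and 92.4%, for arcA-specific genes 19.4%, 79.1% and 100%, and for 6 h against batch across strains 97.0%, 100% and 100%. The share of false calls was highest for phoB at 15 h of PD-005, at 6.56%, and was 6.16% for 6 h against batch across strains. At these depths a 1.5-fold change was recovered for at most 37.3% of the simulated genes in comparisons within a run, except for rpoS-specific genes (58.2%). The simulated spread depended only on a gene's mean level, so libraries that deviated as a whole were not imitated. In a simulated test of 20 lists of 30 genes, the 1 changed list was called and none of the others. The simulated genes varied independently, so this does not show how the list test fares where the genes of a list vary together.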

Results

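Messenger RNA was sequenced from 122 libraries of Escherichia coli K-12 grown either in batch to mid-log phase or in high-density fed-batch culture, where feed is added continuously. By their labels the strains were the BW25113 wild type, 14 single-gene knockouts in BW25113, and an MG1655 strain without fhuA, the gene of the ferrichrome receptor. The libraries formed 59 groups of the same strain, culture, hour and run code (PD-003, PD-004, PD-005, PD-006 or PD-009). 4 groups had 1 library, 47 had 2 and 8 had 3. The labels describe the replicates as biological duplicates and do not say what a run code stands for. Total counts per library ranged from 579920 to 10315000 with a median of 2309500, and 3923 to 4296 of the 4355 listed genes had at least 1 count. The wild type was present in PD-003 and PD-005, the runs that also held the phoB and qseF knockouts. In PD-004, PD-006 and PD-009 each knockout was compared with the other knockouts of its run. No comparison separated the deletion of a gene from other differences of the strain that carried it. Log2 fold changes below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Values after ± are standard errors; strain-specific values, which are smallest pairwise differences, and values from alternative settings are given without one.

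The deleted genes were read first, in every library. The genes basS (6 libraries), kdpE (6), qseB (5), baeR (9) and lsrR (7) had 0 counts in all libraries of their own knockout. The phoB knockout had 12 of 13 libraries at 0 and 1 count in the other, and the same held for glrR, the current name of qseF, in 13 libraries of the qseF knockout. The qseC knockout had 5 of 6 libraries at 0 and at most 1 count, and the tnaA knockout 3 of 4 and at most 2 counts. The arcA gene was at 0 in 5 of 6 libraries of its knockout and at 21 counts, 9.53 CPM (counts scaled to a library total of 1e+06), in the other, against 531 to 1933 CPM in the other strains. The rpoS knockout kept rpoS reads in all 7 libraries, at 368 to 658 CPM, below the 1702 to 6791 CPM of the other libraries. The fhuA gene was at 0 in the 7 MG1655 libraries, but also in 114 of the 115 other libraries. The remaining library had 0.525 CPM. The fhuA counts therefore check no label and show no difference in fhuA between MG1655 and BW25113. Whether the BW25113 strains lacked the gene too was not tested.

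In 4 fed-batch 6 h libraries the deleted gene went against the label. The library labelled lsrB replicate 1 had 127 counts of lsrB, 29.1 CPM; of the other 6 lsrB libraries 5 had 0 and batch replicate 2 had 1. The libraries labelled lsrK replicates 1 and 2 had 14.6 and 53.4 CPM of lsrK, and the other 5 had 0. The library labelled luxS replicate 2 had 1012 counts of luxS, 486 CPM, and 0 counts of lsrK; of the other 5 luxS libraries 4 had 0 counts of luxS and batch replicate 2 had 5, 3.76 CPM. In turn the library labelled lsrK replicate 2 had only 6 counts of luxS, 4.16 CPM, the lowest of all libraries outside the luxS label (median 458 CPM). All 4 were kept under their labels, and each count of genes specific to lsrB, lsrK or luxS is given with and without them.

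**Figure D1:**
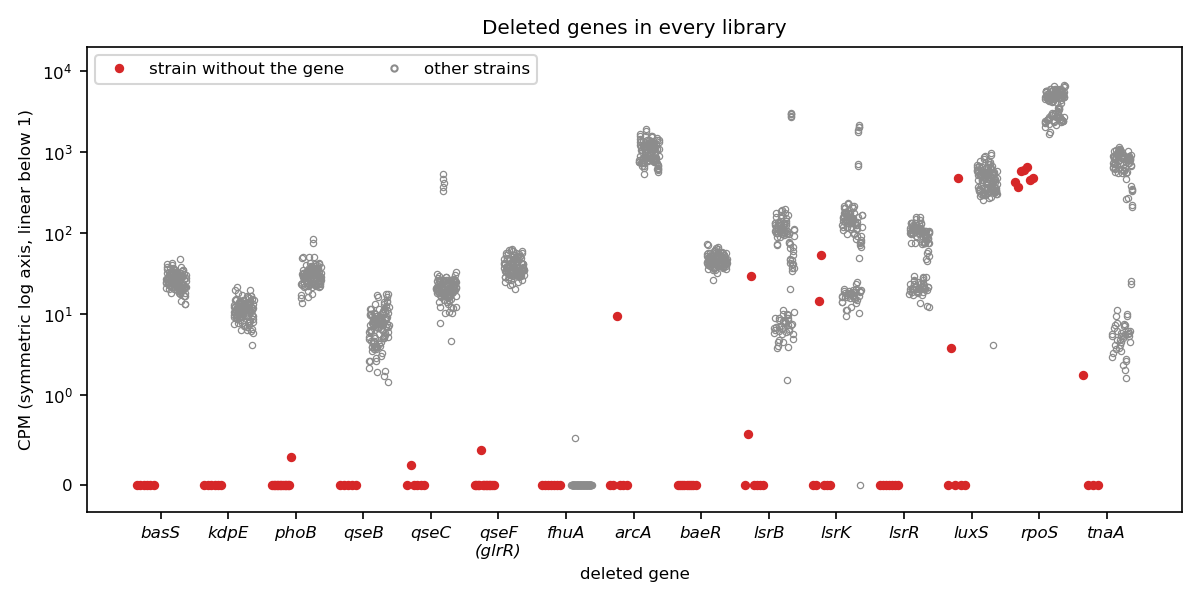
Level of each deleted gene in CPM (symmetric log axis) in every library, with libraries of the strain that lacks the gene as filled points and all other libraries as open points. The rpoS knockout lies at 368 to 658 CPM, and the libraries labelled lsrB, lsrK and luxS hold points above 0; fhuA is near 0 in every strain.

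The wild type was compared between fed-batch culture at 6 h and batch culture to show how high-density growth differed from mid-log growth. In PD-005 (n = 3 and 2), strong rises were in ykgM and ykgO, the zinc-independent copies of ribosomal proteins (9.77 ± 0.30 and 8.19 ± 0.41), zinT, a periplasmic zinc-binding protein (7.70 ± 0.39), prpD of propionate breakdown (7.54 ± 0.51), tnaA, tryptophanase, which makes indole (7.26 ± 0.31), and glcA, the glycolate permease (6.63 ± 0.23). Pyrimidine synthesis and uptake genes fell most: pyrB (-8.45 ± 0.44), pyrI (-7.70 ± 0.32), carA (-5.75 ± 0.34) and uraA (-5.74 ± 0.32). The osmoprotectant transporter gene proV fell by 4.80 ± 0.29 and the nitrate transporter gene narK by 4.48 ± 0.30. In PD-003 (n = 2 and 2, batch at 9 h), the corresponding values were 7.68 ± 0.22 for tnaA, 6.86 ± 0.18 for glcA, 6.71 ± 0.27 for the curli gene csgB and -9.10 ± 0.46 for pyrB. Of 3857 genes tested in PD-005, 965 rose and 903 fell, and of 3740 in PD-003, 943 rose and 885 fell.

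Transport genes for other carbon sources rose together in the wild type: 32 of 34 in PD-005 rose and 1 fell, with the galactose-binding mglB at 4.92 ± 0.19 and malK of maltose uptake at 4.56 ± 0.20 (camera adjusted p = 1.4e-24). All 9 passing genes of 10 for acetate use and the glyoxylate shunt rose, led by actP (5.57 ± 0.20) and acs, acetyl-CoA synthetase (4.48 ± 0.15; adjusted p = 7.7e-13). Of the 10 genes for uptake and synthesis of autoinducer 2 (AI-2), a secreted signal molecule, 8 rose, with lsrA at 4.50 ± 0.36 and lsrB at 4.13 ± 0.27, and none fell. Of 45 flagella and chemotaxis genes 38 fell, with flgE at -3.41 ± 0.25 and the flagellin gene fliC at -2.29 ± 0.15, and 2 rose. Nucleotide synthesis had 20 of 21 genes lower and amino acid synthesis 49 of 56 lower. These 6 lists also passed with an estimated correlation (adjusted p = 0.0043 to 0.038). Ribosomal protein genes fell in 43 of 54 cases (45 adjusted over the list alone), with rpmE falling by 1.58 ± 0.18, but their list had adjusted p = 6.3e-07 with the preset and adjusted p = 0.25 with an estimated correlation. In PD-003 the carbon uptake, acetate, AI-2 and nucleotide lists were called in the same directions (estimated-correlation adjusted p = 0.0002 to 0.022). Flagella had 34 of 44 genes lower with adjusted p = 0.057, and amino acid synthesis 51 of 56 lower with adjusted p = 0.083, with an estimated correlation.

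Later hours of the wild type fed-batch were compared with 6 h. At 15 h in PD-005 (n = 2 and 3), pyrB rose by 7.09 ± 0.44 and pyrI by 5.77 ± 0.33. The rhamnose transporter gene rhaT rose by 4.77 ± 0.22, but stayed at 3.46 to 19.8 CPM in the MG1655 libraries. Iron uptake genes rose in 24 of 34 cases (28 adjusted over the list alone), among them the catecholate siderophore receptors cirA (3.63 ± 0.23) and fepA (3.32 ± 0.22) and fhuE (3.10 ± 0.19; estimated-correlation adjusted p = 0.0002). All 11 acid resistance genes fell, gadA by 2.58 ± 0.36 and the multidrug efflux gene mdtE by 2.71 ± 0.33 (estimated-correlation adjusted p = 0.027), and 19 of 31 genes of the RpoS general stress list fell (26 adjusted over the list alone), katE by 1.25 ± 0.18. Flagella genes rose in 12 of 45 cases (15 adjusted over the list alone), flgD by 2.50 ± 0.29. At 21 h in PD-003 (n = 2 and 2), cirA rose by 4.36 ± 0.18, fepA by 4.20 ± 0.20 and pyrB by 8.30 ± 0.47, while gadA fell by 4.59 ± 0.14 and sodB, the iron superoxide dismutase gene, by 3.89 ± 0.16. There, 26 iron genes rose and 1 fell, all 11 acid genes fell and 20 of 44 flagella genes rose, while 20 of 31 RpoS genes fell with adjusted p = 0.091 under an estimated correlation. In all, 452 genes changed at 15 h and 1019 at 21 h. The first count was 213 or 218 without wild type 15 h replicate 2 or 1, and the second 539 without 6 h replicate 2 and 676 without 21 h replicate 2.

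Culture effects were then tested across strains, with each strain and run as a block and its replicates summed. Between fed-batch and batch at 6 h (15 blocks of 14 strains, 62 libraries), 3128 of 3905 genes changed, 848 of them at least 2-fold, and 914 rose and 841 fell with the same sign in all 15 blocks. Among the 10 strongest rises by the naming rule were ykgM (8.57 ± 0.39), zinT (7.94 ± 0.45), prpD (7.50 ± 0.39) and the xylose-binding gene xylF (6.06 ± 0.19). Among the 10 strongest falls were pyrB (-8.06 ± 0.12), uraA (-5.56 ± 0.09), codB (-5.06 ± 0.11) and mqo (-4.71 ± 0.13). All 54 ribosomal protein genes fell, with a median log2 fold change of -0.60, 46 of 48 flagella genes fell, 33 of 34 carbon uptake genes rose and 4 of 4 ribosome hibernation genes rose (raiA 2.43 ± 0.09). With an estimated correlation the carbon uptake and nucleotide lists held (adjusted p = 0.041 and 0.011), and the ribosomal (adjusted p = 0.3), flagella (adjusted p = 0.83) and hibernation (adjusted p = 0.2) lists did not. Between 15 h and 6 h of fed-batch (15 blocks of 15 strains, 65 libraries), 1894 of 3891 genes changed, 135 of them at least 2-fold. pyrB rose by 6.50 ± 0.20, cirA by 3.88 ± 0.13 and fiu by 3.23 ± 0.14, and gadA fell by 3.06 ± 0.28 and sodB by 2.40 ± 0.15. Iron uptake had 33 of 34 genes higher and none lower (estimated-correlation adjusted p = 7.8e-05). Acid resistance had 11 of 11 lower, RpoS stress 30 of 31 lower, heat shock 14 of 17 lower and flagella 32 of 43 higher. With an estimated correlation their adjusted p was 0.15, 0.2, 0.28 and 0.83.

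**Figure D2:**
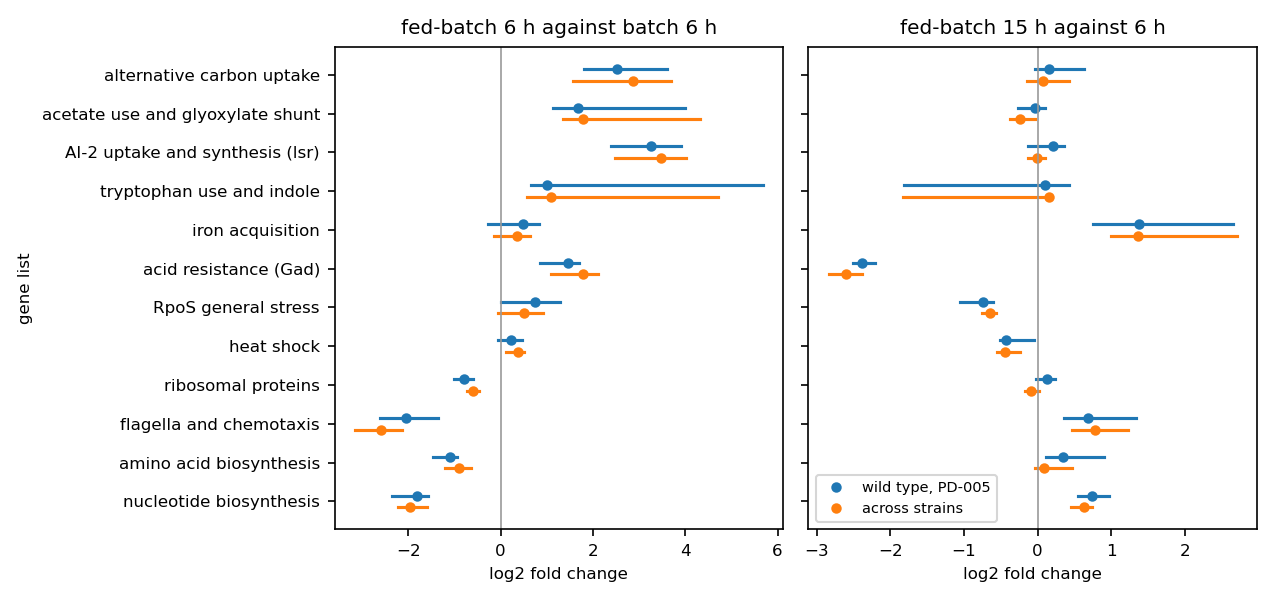
Median log2 fold change of 12 fixed gene lists in the wild type (PD-005) and across strains, for fed-batch 6 h against batch 6 h and for fed-batch 15 h against 6 h. Points are list medians and bars span the lower and upper quartiles of the member genes; the ribosomal list lies at -0.60 across strains at 6 h.

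PhoB is the response regulator of phosphate starvation, and its knockout was compared with the wild type of the same run in 3 conditions of PD-003 (n = 2 per group) and 3 of PD-005 (n = 2 or 3). The phosphate-binding gene pstS fell in all 6. It changed by -3.49 ± 0.34, -2.16 ± 0.29 and -4.04 ± 0.25 at batch, fed-batch 6 h and 21 h of PD-003 and by -3.47 ± 0.21, -2.73 ± 0.21 and -3.56 ± 0.22 at batch, 6 h and 15 h of PD-005. The transporter gene pstC fell by 2.57 ± 0.38 in PD-003 batch and 1.98 ± 0.22 in PD-005 batch. phoR, the sensor kinase gene directly downstream of phoB, rose by 2.08 ± 0.22 to 2.85 ± 0.18. phoB itself was at least 14.3-fold lower in PD-003 batch and at least 120-fold lower in PD-005 fed-batch 6 h, against a floor of 3 counts over the group. The Pho list was lower in all 6 conditions (estimated-correlation adjusted p = 7.3e-05 to 0.035), although at 21 h of PD-003 its median was 0.01, with 6 of 22 genes lower and 1 higher. Flagella genes were lower at 21 h, where 18 of 44 fell (28 adjusted over the list alone; flgC -3.86 ± 0.41, flgD -3.31 ± 0.27, estimated-correlation adjusted p = 0.00019), and in PD-005 batch, where 8 of 45 fell (20 adjusted over the list alone; fliC -1.94 ± 0.15). Acid resistance genes fell in 9 of 11 cases at 21 h (gadA -1.49 ± 0.14), and heat shock genes rose in 8 of 17 cases at fed-batch 6 h of PD-005 (15 adjusted over the list alone; groL 0.99 ± 0.15; estimated-correlation adjusted p = 0.0037). groL lost its call with only the libraries of the compared groups (0.95, adjusted p = 0.422) and without the PD-005 libraries under 1500000 counts (0.58, adjusted p = 0.676). The glycine cleavage gene gcvP rose in PD-003 batch (1.12 ± 0.13) and at 21 h (1.26 ± 0.14).

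The numbers of genes that differed between the phoB knockout and the wild type were 31, 12 and 95 at batch, 6 h and 21 h of PD-003 and 29, 42 and 22 at batch, 6 h and 15 h of PD-005, and they moved with single libraries and with the setting. With the replicate number as a block the PD-005 counts were 348 in batch and 342 at 6 h, and with only the libraries of the compared groups they were 5 at 6 h and 414 at 15 h. DESeq2 gave 103 and limma on the deposited log2 TPM 26 at 6 h of PD-005. In PD-003 limma gave 19 in batch and 59 at 21 h, and the compared groups alone 18, 27 and 55 in batch, at 6 h and at 21 h. In PD-003 batch they were 16 and 18 without phoB replicates 2 and 1 and 18 and 20 without wild type replicates 2 and 1. At 6 h they were 6 and 7 without replicate 2 of the wild type and of phoB. At 21 h they were 37 and 171 without phoB replicates 2 and 1 and 38 and 169 without wild type replicates 2 and 1. In PD-005 batch they were 14 and 15 without wild type replicates 2 and 1 and 17 and 18 without phoB replicates 2 and 3. At 15 h the count was 14 without phoB replicate 2. At 6 h it was 15, 16 and 143 without wild type replicates 2, 1 and 3 and 17 and 391 without phoB replicates 1 and 2.

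QseF is a response regulator listed as glrR, and the qseF knockout was compared with the wild type under the same scheme, except that its PD-003 batch libraries were taken at 6 h and the wild type's at 9 h. Xylose transport genes were higher in fed-batch: xylE, the proton symporter, by 3.77 ± 0.27 at 6 h and 5.96 ± 0.23 at 21 h of PD-003 and by 3.15 ± 0.23 at 6 h and 5.83 ± 0.26 at 15 h of PD-005, and xylF, the binding protein of the ABC transporter, by 2.47 ± 0.17, 3.85 ± 0.16, 1.99 ± 0.18 and 4.39 ± 0.23. In PD-005 batch xylE, a value chosen after it was seen, was not detectably different (0.53 ± 0.40), at 4.21 and 5.82 CPM in the 2 knockout libraries and 3.22 and 3.19 CPM in the 2 of the wild type. The xyloside genes yicJ (4.69 ± 0.27) and yagG (3.60 ± 0.25) rose at 21 h, while xylA, xylose isomerase, fell by 1.20 ± 0.23 at 6 h of PD-003 and by 0.87 ± 0.22 at 6 h of PD-005. The xylA call ended without any one of the 4 libraries in PD-003 (adjusted p = 0.0521 to 0.0998) and, in PD-005, without wild type replicate 1 or 2 or qseF replicate 2 or 3 (adjusted p = 0.0987 to 0.347). It also ended in limma on the deposited log2 TPM in both runs (adjusted p = 0.0806 and 0.158) and, in PD-005, with only the libraries of the compared groups (adjusted p = 0.326). glnB, the PII protein gene directly downstream of glrR, rose by 1.21 ± 0.13 at 6 h and 1.33 ± 0.15 in batch of PD-005, and ubiK, of ubiquinone synthesis, fell in all 6 conditions, by 4.65 ± 0.26 to 6.45 ± 0.37. Whether ubiK fell through the deletion or through another difference of the strain was not tested. glrR was at least 50.1-fold to at least 116-fold lower in the 5 conditions where the knockout had 0 counts. The regulator gene lrhA fell by 1.64 ± 0.18 at 21 h and 1.07 ± 0.16 at 6 h of PD-005. Of the fixed lists only the TCA cycle at 6 h of PD-005, with 10 of 16 genes higher (13 adjusted over the list alone; gltA 0.65 ± 0.11), passed with an estimated correlation (adjusted p = 0.034). gltA lost its call with only the libraries of the compared groups (0.63, adjusted p = 0.0938) and without the PD-005 libraries under 1500000 counts (0.61, adjusted p = 0.26). The counts were 6, 23 and 37 genes in PD-003 and 7, 56 and 15 in PD-005. With only the libraries of the compared groups they were 14 at 6 h and 40 at 15 h of PD-005, and in limma on the deposited log2 TPM 12 at 6 h and 23 at 21 h of PD-003. The edgeR counts were 11 without wild type replicate 2 and 12 and 37 without qseF replicates 2 and 1 at 6 h of PD-003. At 21 h they were 22 and 106 without wild type replicates 2 and 1 and 23 without either qseF replicate, and in PD-005 batch 14 without qseF replicate 1.

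**Figure D3:**
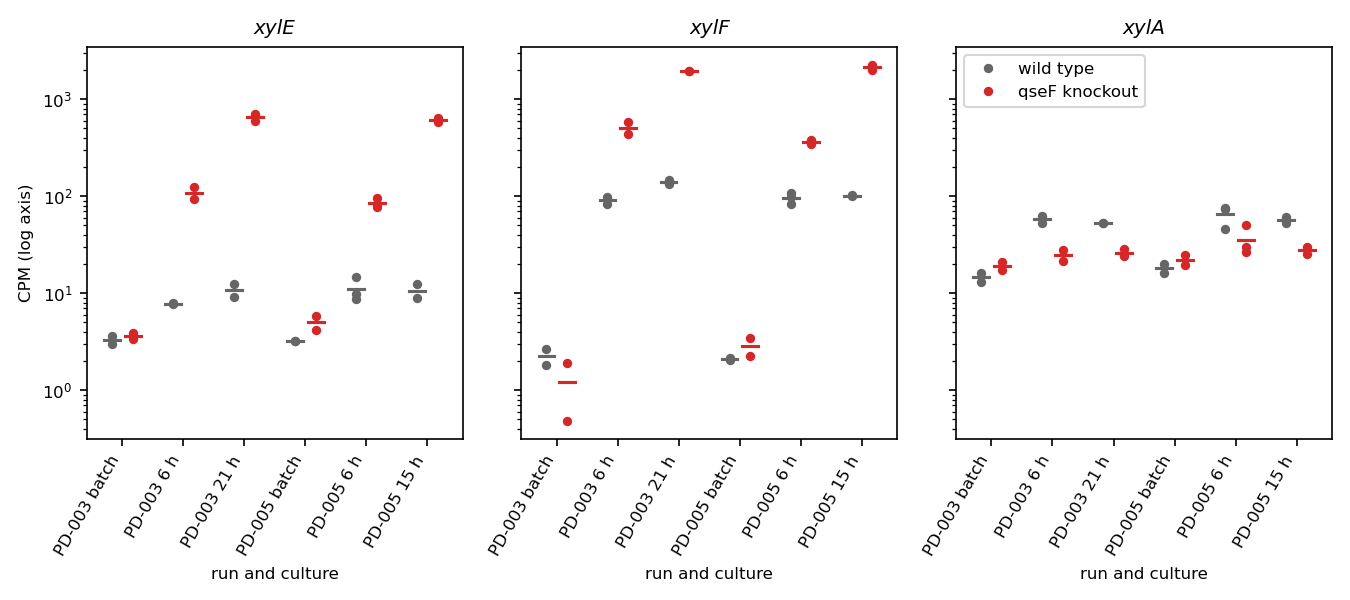
CPM of xylE, xylF and xylA (log axis) in each library of the wild type and of the qseF knockout in PD-003 and PD-005, by culture and hour; points are libraries and short bars are group means. At 21 h the 2 knockout libraries hold 593 and 708 CPM of xylE, against 9.19 and 12.5 CPM in the wild type.

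The MG1655 strain was compared with the BW25113 wild type in PD-005 (n = 2 or 3). BW25113 carries deletions in the arabinose and rhamnose operons and in lacZ, and its list of 7 such genes was higher in MG1655 in all 3 conditions. araA, at 0 counts in the wild type, was at least 10.1-fold, 83.8-fold and 30.0-fold higher in batch, fed-batch 6 h and 15 h, and lacZ rose by 2.92 ± 0.51, 3.55 ± 0.42 and 3.25 ± 0.55. In batch the lacZ value was 2.37 (adjusted p = 0.176) without wild type replicate 2. Outside this list, tabA, a biofilm-linked gene, fell by 3.66 ± 0.19, 4.52 ± 0.23 and 4.61 ± 0.23. mhpD of phenylpropionate breakdown, in a gene cluster beside the lac genes, fell by 3.63 ± 0.27, 3.04 ± 0.30 and 2.90 ± 0.31. hsdR, the restriction endonuclease gene, rose by 1.25 ± 0.13 to 1.46 ± 0.13, and pheA fell by 1.56 ± 0.17 in batch. Flagella genes fell in 10 of 45 cases in batch (29 adjusted over the list alone; fliC -1.77 ± 0.15; estimated-correlation adjusted p = 2.4e-06) and in 11 of 45 at 15 h (17 adjusted over the list alone; flgB -3.35 ± 0.36). At 15 h 5 of 16 curli and fimbriae genes fell (14 adjusted over the list alone, csgA -2.43 ± 0.32) and rhaT fell by 5.68 ± 0.26. Over all conditions rhaT was at 3.46 to 19.8 CPM in the MG1655 libraries, and at 3.19 to 1298 CPM in the wild type libraries of both runs. Whether this difference came from the rhamnose operon deletion of BW25113 was not tested. The counts were 52, 28 and 38 genes. With the replicate number as a block there were 152 at 6 h, with only the libraries of the compared groups 30 in batch and 60 at 15 h, and in limma on the deposited log2 TPM 33 in batch. In batch the edgeR counts were 18 and 21 without wild type replicates 2 and 1 and 33 without MG1655 replicate 2, and at 15 h 58 without MG1655 replicate 1. Leaving out the 8 PD-005 libraries under 1500000 counts, a choice made after seeing the data, gave 82 genes in batch, and for phoB 19 in batch and 10 at 6 h and for qseF 20 at 6 h.

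flu, which encodes the phase-variable surface adhesin antigen 43, was higher than in the wild type in every condition of all 3 strains. It rose by 4.36 ± 0.21 to 4.66 ± 0.25 in the phoB knockout, by 4.01 ± 0.19 to 4.32 ± 0.21 in the qseF knockout and by 3.94 ± 0.22 to 4.36 ± 0.25 in MG1655. The wild type libraries held 32.5 to 86.9 CPM (n = 13), the phoB libraries 735 to 1676 CPM (n = 13) and the MG1655 libraries 684 to 1609 CPM (n = 7). In runs without a wild type, chosen after the values were seen, flu was at 728 to 1177 CPM in the basS strain (n = 6) and 718 to 1665 CPM in the qseC strain (n = 6), but at 66.0 to 176 CPM in the qseB strain (n = 5) and 29.6 to 41.0 CPM in the rpoS strain (n = 7). The library labelled luxS fed-batch 6 h replicate 2 had 938 CPM of flu against 148 to 168 CPM in the other 5 of that label, and the library labelled lsrK replicate 2 had 141 CPM against 845 to 1709 CPM in the other 6.

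**Figure D4:**
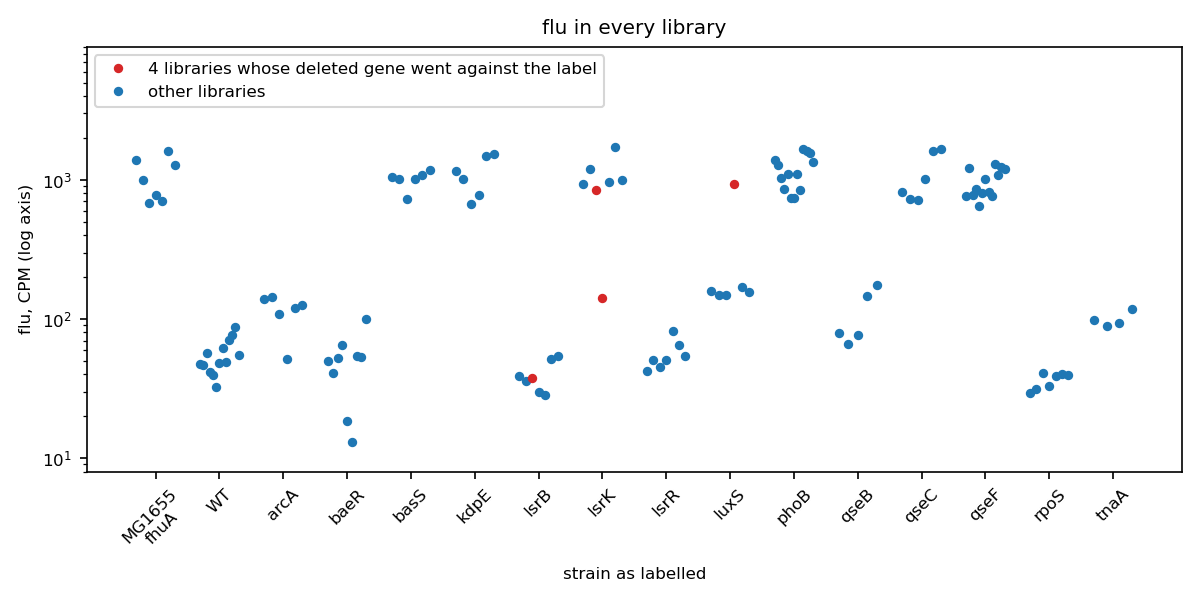
CPM of flu (log axis) in every library by labelled strain; red points are the 4 libraries whose deleted gene went against the label. The wild type lies at 32.5 to 86.9 CPM and the phoB knockout at 735 to 1676 CPM.

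The change between early and late fed-batch was tested for differences between each of these strains and the wild type. With phoB at 21 h, hdeB (-2.74 ± 0.39), slp (-1.80 ± 0.29), hdeA (-1.64 ± 0.22) and pstS (-1.89 ± 0.41) differed downward from the wild type change and gcvP upward (1.42 ± 0.20). The pstS call ended without each of 7 of the 8 libraries, wild type 6 h replicate 1 being the exception (adjusted p = 0.0518 to 0.313), and the slp call without replicate 2 of the wild type or of phoB at 21 h (adjusted p = 0.0543 and 0.088). That of pstS also ended with the replicate number as a block (adjusted p = 0.0588) and in limma on the deposited log2 TPM (adjusted p = 0.0516). With only the libraries of the compared groups it ended too (adjusted p = 0.0506). With qseF, the difference was 2.19 ± 0.43 for xylE and 3.01 ± 0.37 for yagH at 21 h, and 2.67 ± 0.35 for xylE, 2.41 ± 0.27 for xylF and 3.06 ± 0.56 for yicJ at 15 h, while metE differed by -1.35 ± 0.17 at 15 h and csgA by -1.59 ± 0.20 at 21 h (adjusted p = 0.0613 in limma on the deposited log2 TPM). The xylE call at 21 h ended without wild type 6 h replicates 1 and 2 or 21 h replicate 2, left out singly (adjusted p = 0.0703, 0.313 and 0.108), and the yicJ call without wild type 6 h replicate 3 or 15 h replicate 2 (adjusted p = 0.385 and 0.11). In limma on the deposited log2 TPM the xylE call at 21 h ended too (adjusted p = 0.0613). With MG1655 at 15 h, rhaT differed by -4.68 ± 0.33, csgB by -2.83 ± 0.56 and csgA by -2.52 ± 0.41. csgA had adjusted p = 0.0736 and 0.132 without MG1655 6 h or 15 h replicate 2, and csgB lost its call without each of 8 of the 9 libraries, wild type 6 h replicate 3 being the exception (adjusted p = 0.0636 to 0.891). In limma on the deposited log2 TPM both lost their MG1655 calls (csgA adjusted p = 0.0849, csgB adjusted p = 0.999). In DESeq2 csgB did so too (adjusted p = 0.278). These tests passed 17 and 1 genes for phoB at 21 h and 15 h (the 1 being metE, -1.10 ± 0.18), 27 and 12 for qseF and 4 for MG1655. With the replicate number as a block there were 93 for phoB and 19 for qseF at 15 h. DESeq2 gave 44 and 21 for phoB and 51 and 20 for qseF at 21 h and 15 h, and limma on the deposited log2 TPM gave 10 for phoB and 8 for qseF at 21 h and 2 for MG1655. With only the libraries of the compared groups there were 60 for qseF at 21 h and 0 for phoB at 15 h. For phoB at 21 h the edgeR count was 7 and 82 without phoB 21 h replicates 2 and 1, 8 without either phoB 6 h replicate, and 9 and 31 without wild type 21 h replicates 2 and 1. For phoB at 15 h it was 0 without any single 15 h library of either strain, 38 without wild type 6 h replicate 3 and 207 without phoB 6 h replicate 2. For qseF at 21 h it was 5 without wild type 6 h replicate 2, 8 and 75 without wild type 21 h replicates 2 and 1, 7 without qseF 21 h replicate 2, and 10 and 87 without qseF 6 h replicates 2 and 1. At 15 h it was 6 without wild type 6 h replicate 3 or 15 h replicate 2. For MG1655 it was 2 without its 6 h or 15 h replicate 2.

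In PD-004 each of 4 knockouts was set against the other 3, and a gene was specific to a strain when it differed from all others in the same direction on the mean of batch, 6 h and 15 h. Values are the smallest of the 3 log2 differences, with n = 5 or 6 libraries per strain. The basS strain, without the sensor kinase of lipid A modification, had 525 specific genes, 231 higher and 294 lower, with hdfR (1.55) and the porin gene ompF (1.18) higher and the curli genes csgB (-2.33), csgE (-2.29) and csgD (-1.62), maoP (-1.83) and gadE (-1.37) lower. csgB had adjusted p = 0.0919 without qseC batch replicate 1, and gadE was -0.81 (adjusted p = 0.114) without qseB 15 h replicate 1. There, 24 of 31 RpoS stress genes (29 adjusted over the list alone) and 10 of 11 acid resistance genes (11 adjusted over the list alone) were lower. Of the 14 genes of the BasRS lipid A list, which holds basS itself, 2 were lower (2 adjusted over the list alone) and 0 higher. The kdpE strain, without the regulator of potassium uptake, had 33, of which 32 were higher, and 27 of these were among the 50 flagella and chemotaxis genes (45 adjusted over the list alone): tap (1.35), tar (1.30) and fliC (1.11). Of 9 measured potassium uptake genes 1 was lower and 0 higher, with the same counts adjusted over the list alone. The qseB strain had 25: qseC, its partner gene downstream, was higher (4.36), and cyoB, a subunit of cytochrome bo oxidase, was lower (-6.32), at 4.51 to 22.0 CPM against 780 to 3878 CPM in the libraries of all other strains. cyoA was lower too (-2.39), and so was cyoC (-2.44), but the latter value is the difference from the kdpE strain, where cyoC was itself at only 18.2 to 50.8 CPM, against 652 to 883 CPM in the basS strain and 3.61 to 11.1 CPM in the qseB strain. The insH copies that were higher there share reads and are uncertain. The qseC strain had 32, with cbrB (3.23), cbrA (3.12) and creD (1.83), genes of the CreBC regulon, higher and flgB (-2.52) and flgE (-1.79) lower. 26 of its 27 lower genes were on the flagella list (39 adjusted over the list alone). The kdpE count was 14 without kdpE 6 h replicate 1, where tar also lost its call (adjusted p = 0.152). tap lost its call without kdpE 6 h replicate 1 or 15 h replicate 2 or qseB 6 h or 15 h replicate 1 (adjusted p = 0.0571 to 0.768). The qseC count was 15 without qseB 6 h replicate 1, and flgB lost its call without that library (-1.03, adjusted p = 1) or without qseC 6 h or 15 h replicate 1 (adjusted p = 0.0865 and 0.0802). On fed-batch conditions alone the kdpE and qseC counts were 3 and 8; fliC (0.38), tap (0.55) and tar (0.63) were then no longer called for kdpE (adjusted p = 1 each), nor flgB for qseC (-2.59, adjusted p = 0.633).

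In PD-006 the lsrB, lsrR and rpoS knockouts were compared (n = 7 libraries each; the batch libraries of rpoS were taken at 9 h and the others at 6 h). Without the AI-2 repressor LsrR, 70 genes were specific, of which 67 were higher. Transport operon genes were among the latter: lsrB (5.14), lsrD (4.80) and lsrA (4.76), with flgB (2.66) and fliA (2.44). The AI-2 kinase gene lsrK, beside the deleted lsrR, was higher too (4.36). Whether lsrK rose through the missing repressor or through the deletion beside it was not tested. Of 49 flagella and chemotaxis genes 46 were higher (49 adjusted over the list alone). The strain labelled as the knockout of rpoS, the general stress sigma factor gene, which kept rpoS reads in all its libraries, had 1676 specific genes. Genes of the general stress response were lower, such as yciG (-7.92), poxB, pyruvate oxidase (-5.74), katE, catalase (-5.17), and osmY (-4.21), and colanic acid capsule genes were higher, wcaF (5.67), wcaA (4.37) and the activator gene rcsA (3.99). katE and osmY were chosen after their values were seen. All 31 RpoS stress genes and all 11 acid resistance genes were lower, and all 21 colanic acid genes and all 9 ATP synthase genes were higher, with the same counts adjusted over the list alone. The lsrB strain had 1 specific gene, ppa, inorganic pyrophosphatase (-1.17), and lsrB itself missed the threshold (-5.15, adjusted p = 0.054). Without the 4 libraries that went against their labels, of which only lsrB 6 h replicate 1 belonged here, it had 17, and it had 2 without 6 h replicate 2 or 3. The lsrB gene passed without 6 h replicate 1 (-7.81, adjusted p = 2.2e-12). It also passed without 6 h replicate 2 or 3 (adjusted p = 0.0093 and 0.0026) and on fed-batch conditions alone (adjusted p = 0.0049).

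In PD-009 the arcA, lsrK, luxS and tnaA knockouts were compared (n = 4 to 7 libraries each). The arcA strain, without the regulator of respiration, had 45 specific genes: the putrescine breakdown genes puuC and puuD (1.53 each), cirA (1.64), fadD of fatty acid uptake (1.51) and sucA of the TCA cycle (0.60, chosen after its value was seen) were higher, with 5 of 16 TCA cycle genes higher (9 adjusted over the list alone), and cydA and cydB of cytochrome bd oxidase were lower (-0.79 and -0.72). Of 22 aerobic respiration genes 4 were lower (5 adjusted over the list alone) and 0 higher. The lsrK strain, labelled as without the AI-2 kinase, had 57, of which 55 were higher, and 47 of these were among the 50 flagella and chemotaxis genes (50 adjusted over the list alone): tar (3.85), motA (3.80) and fliC (3.25). tar had adjusted p = 0.311 without lsrK 6 h replicate 1. lsrK (-6.03) was lower, with adjusted p = 0.0571 without luxS batch replicate 2 and -3.10 (adjusted p = 1) without luxS 6 h replicate 1, and so was nfi (-3.31), at -1.63 (adjusted p = 1) without the latter library. The tnaA strain had 2, tnaA (-9.63) and lrhA (-0.84). For luxS, the AI-2 synthase gene, no gene passed in edgeR, where 66 had an unadjusted p below 0.05, and 8 passed in DESeq2. Both lsrK 6 h libraries were among the 4 that went against their labels, so leaving these 4 out removed that group. Differences from lsrK then rested on batch and 15 h alone, unlike those in the main counts. Without the 4 libraries that went against their labels, a choice made after seeing the data, luxS had 30, among them luxS (-10.43) and the acid resistance genes gadA (1.40) and gadB (1.29), and lsrK 72. The lsrK count was 22 without lsrK 6 h replicate 1, and 16 on fed-batch conditions alone, where motA (1.79, adjusted p = 0.109) and nfi (-2.71, adjusted p = 0.161) lost their calls. The luxS count was 14 and 1 without luxS 6 h replicates 2 and 1 and 2 without lsrK 6 h replicate 2. The tnaA count was 1 without lsrK batch replicate 2, where lrhA had adjusted p = 0.0517.

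The baeR knockout, without an envelope stress regulator, was grown for 12 h in PD-006 and PD-009. Against the other knockouts in batch (n = 2), the type 1 fimbria genes fimA (2.94 in PD-006 and 3.48 in PD-009), fimI (2.80 and 3.44) and fimC (2.57 and 3.29) were higher, with the envelope stress gene cpxP at 2.50 in PD-006 and, chosen after its value was seen, 2.42 in PD-009. The PD-009 call of cpxP ended without either batch replicate of arcA, lsrK or luxS (adjusted p = 0.0532 to 0.0978) and without baeR batch replicate 2 (0.67, adjusted p = 0.59), and also with the replicate number as a block (2.39, adjusted p = 0.0824). A run of 31 neighbouring genes from yjhV to fimE, which holds the iron citrate genes fecE to fecI and the fimbria recombinase genes fimB and fimE, had 3 counts in all over the 9 baeR libraries, where 13829 were expected at the median CPM of the other strains. The run was singled out after its values were seen. In all, 469 genes were specific in PD-006, 27 of the 150 lower ones in this run of genes, and 185 in PD-009, 16 of the 49 lower ones in it. The latter count was 100 without baeR batch replicate 2, and 114 and 119 without luxS batch replicates 1 and 2. The other strains were at 6 h or 9 h in batch, so strain and hour were not separated here.

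**Figure D5:**
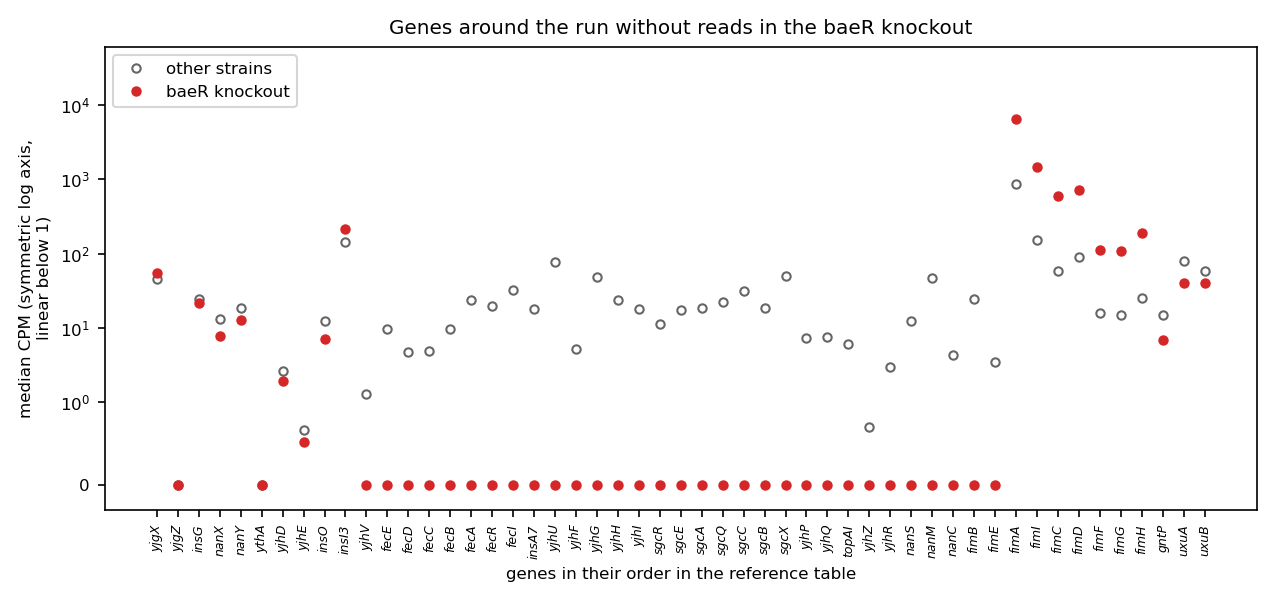
Median CPM (symmetric log axis) of 31 neighbouring genes from yjhV to fimE and of 10 genes on each side, in gene order, in the 9 baeR libraries (filled points) and in the other libraries (open points). The 31 genes have 3 counts in all in the baeR libraries, and fimA beyond their end has a median of 6487 CPM there.

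The baeR strain was also compared between cultures at 12 h. In PD-006 (n = 2 and 2), ykgM (8.83 ± 0.25), zinT (8.68 ± 0.29) and znuA, the zinc-binding transporter gene (5.13 ± 0.11), rose in fed-batch, and pyrB (-6.29 ± 0.33), carA (-6.04 ± 0.23) and fliA (-6.35 ± 0.30) fell. flgB went from 1239 counts to 3. In PD-009 (n = 2 and 2), ykgM (9.50 ± 0.41), tnaA (7.98 ± 0.57) and glcA (7.02 ± 0.41) rose and narK (-5.51 ± 0.81) and mqo (-3.38 ± 0.30) fell. In PD-006 tnaA, chosen after its value was seen, fell by 1.79 ± 0.43, and by 1.43 (adjusted p = 0.075) without fed-batch replicate 1. At 18 h against 12 h (n = 1 and 2, so the 18 h library was taken to vary like the other groups), cirA (4.13 ± 0.29) and fepA (3.12 ± 0.21) rose and sodB (-2.22 ± 0.26) fell. The counts were 1728, 1114 and 46 genes. The last was 75 in DESeq2 and 92 with only the libraries of the compared groups, and without 12 h fed-batch replicate 1 of PD-009 the last 2 counts were 739 and 28.

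Groups of the same strain, culture and hour in 2 runs were compared as a measure of the spread between runs. For the baeR fed-batch at 12 h 1909 of 4031 genes differed between PD-009 and PD-006 (n = 2 and 2): the galactitol genes gatB (9.60 ± 0.55) and gatD (9.56 ± 0.20), malK (9.19 ± 0.55) and tnaA (8.28 ± 0.41) were higher in PD-009, and alaE (-6.85 ± 0.44) was lower. In baeR batch 63 genes differed, with narK at 3.57 ± 0.46 and narG at 2.37 ± 0.27. With the replicate number as a block only 2 genes did, and narK (2.52, adjusted p = 1) and narG (2.25, adjusted p = 0.133) lost their calls. For qseF batch 33 differed between PD-005 and PD-003, with the zinc genes zinT (-4.60 ± 0.35), ykgM (-4.00 ± 0.38) and znuA (-2.74 ± 0.21) lower in PD-005. For the wild type at fed-batch 6 h 113 differed, with trpA at -1.05 ± 0.21 and tsf, elongation factor Ts, at -0.89 ± 0.16. The tsf call ended without PD-003 replicate 1 or PD-005 replicate 1 (adjusted p = 0.0719 and 0.0603), and the trpA call without either PD-003 replicate or PD-005 replicate 1 (adjusted p = 0.0603 to 0.0624). For phoB and qseF at 6 h no gene passed in edgeR, where 390 and 233 had an unadjusted p below 0.05, and 22 and 3 passed in DESeq2. With the replicate number as a block there were 29 genes for the wild type, 43 for phoB, 15 for qseF batch and 1269 for baeR fed-batch, and DESeq2 gave 215 for the wild type. The wild type count was 1 and 6 without PD-003 replicates 1 and 2 and 0, 27 and 558 without PD-005 replicates 1, 2 and 3. The phoB count was 1 and 304 without PD-005 replicates 1 and 2, and the qseF fed-batch count was 28 without PD-005 replicate 2. The qseF batch count was 20 and 10 without PD-005 replicates 1 and 2 and 13 without PD-003 replicate 1. The baeR batch count was 22 without PD-009 replicate 1 and 24 without PD-006 replicate 2.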

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

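The values in this part came from tests chosen before the data were examined: each measures whether the late minus early fed-batch change differed between a strain and the wild type. No technical or biological explanation was tested for them.

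The phoB change between 6 h and 21 h of PD-003 differed from that of the wild type for 17 genes, with hdeB at -2.74, hdeA at -1.64, slp at -1.80, pstS at -1.89 and gcvP at 1.42. The count was 31 and 9 without wild type 21 h replicates 1 and 2, 8 without either phoB 6 h replicate, and 82 and 7 without phoB 21 h replicates 1 and 2. pstS lost its call without each of 7 libraries, all except wild type 6 h replicate 1 (adjusted p = 0.0518 to 0.313), and slp without replicate 2 of either strain at 21 h (adjusted p = 0.0543 and 0.088). The pstS call also ended with the replicate number as a block (adjusted p = 0.0588) and in limma on the deposited log2 TPM (adjusted p = 0.0516). With only the libraries of the compared groups it ended too (adjusted p = 0.0506). Between 6 h and 15 h of PD-005 the difference was called for 1 gene, metE, the cobalamin-independent methionine synthase gene, at -1.10. That count was 0 without any single 15 h library of the wild type or of phoB, where metE had adjusted p = 0.0596 to 0.256, and it was 38 without wild type 6 h replicate 3 and 207 without phoB 6 h replicate 2. Where it was 0, it was so in edgeR; with all libraries DESeq2 called 21, and the replicate number as a block gave 93. For PD-003 DESeq2 called 44 and limma on the deposited log2 TPM 10.

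The qseF change differed for 27 genes in PD-003, with xylE at 2.19, yagH of xyloside use at 3.01 and csgA at -1.59, and for 12 in PD-005, with xylE at 2.67, xylF at 2.41, yicJ at 3.06 and metE at -1.35. In PD-003 the count was 5 without wild type 6 h replicate 2, 75 and 8 without wild type 21 h replicates 1 and 2, 87 and 10 without qseF 6 h replicates 1 and 2, and 7 without qseF 21 h replicate 2. There xylE lost its call without wild type 6 h replicate 1 or 2 or 21 h replicate 2 (adjusted p = 0.0703, 0.313 and 0.108). In limma on the deposited log2 TPM xylE and csgA of PD-003 lost their calls (adjusted p = 0.0613 each). In PD-005 the count was 6 without wild type 6 h replicate 3 or 15 h replicate 2, and without the same libraries yicJ had adjusted p = 0.385 and 0.11. In PD-003 DESeq2 called 51, limma 8 and edgeR with only the libraries of the compared groups 60; in PD-005 DESeq2 called 20 and the replicate block 19.

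The MG1655 change differed for 4 genes, among them rhaT at -4.68 and the curli subunit genes csgB at -2.83 and csgA at -2.52. The count was 2 without MG1655 6 h replicate 2 or 15 h replicate 2, where csgA had adjusted p = 0.0736 and 0.132. csgB lost its call without each of 8 of the 9 libraries, wild type 6 h replicate 3 being the exception (adjusted p = 0.0636 to 0.891). Limma on the deposited log2 TPM called 2, and there csgA (adjusted p = 0.0849) and csgB (adjusted p = 0.999) lost their calls. In DESeq2 csgB did so too (adjusted p = 0.278).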

How the results depend on the processing

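Leaving out the 4 libraries whose deleted gene went against the label, or the 8 PD-005 libraries under 1500000 counts, was chosen only after the data were seen. The other alternatives were planned. Without those 4 libraries no lsrK 6 h library remained, so differences from lsrK then rested on batch and 15 h alone. Relative log expression scaling left every count of changed genes within 1.5 times, moved the share of higher calls at most from 50.4% to 40.7%, in the wild type between runs, and moved the median of all genes by at most 0.03. The counts across strains stayed within 1.5 times under every alternative run for them. Many counts under 100 genes within a run moved when single libraries were left out or when only the libraries of the compared groups were fitted. Over the 232 named gene values, 1595 of 1626 recomputed values kept their direction and side of the threshold under the other settings, 27 lost the call and 4 gained it; none reversed. The calls lost were those of xylA, pstS (interaction), csgA and csgB (interactions), xylE (interaction, PD-003) and metE (interaction with phoB), of fliC, tap and tar for kdpE, flgB for qseC and motA and nfi for lsrK on fed-batch conditions alone, of groL (phoB) and gltA (qseF) at 6 h of PD-005 with fewer libraries, and of cpxP (PD-009), narG and narK under the replicate block; lsrB gained its call in its own knockout. With single libraries left out, 1723 of 1791 values kept both, 65 lost the call, 3 gained it and none reversed. In both tallies a strain-specific value whose pairwise signs disagreed was given no direction, so it could not count as reversed. Values without an adjusted p under a setting were left out. By the naming rule most of these genes were picked for large changes or a low adjusted p in the same data. Their calls were therefore likely to hold, and the tallies do not carry over to genes not named. Where a count below moved, the cause was not tested.

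DESeq2 gave 44 genes for the interaction of phoB in PD-003 (17 in edgeR), 51 for that of qseF in PD-003 (27), 21 for phoB (1) and 20 for qseF (12) in PD-005, 103 for phoB at 6 h of PD-005 (42), 2 for lsrB (1), 8 for luxS (0), 75 for baeR at 18 h (46), and between runs 215 for the wild type (113), 22 for phoB (0) and 3 for qseF at 6 h (0). Limma on the deposited log2 TPM gave 19 for phoB in PD-003 batch (31), 59 at 21 h (95) and 26 at 6 h of PD-005 (42), 12 for qseF at 6 h (23) and 23 at 21 h (37) of PD-003, 33 for MG1655 in batch (52), and interactions of 10 for phoB (17) and 8 for qseF (27) in PD-003 and 2 for MG1655 (4). With no filter on low counts, lsrB had 2 (1) and phoB between runs 1 (0).

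With only the libraries of the compared groups, phoB had 18 in batch (31), 27 at 6 h (12) and 55 at 21 h (95) of PD-003 and 5 at 6 h (42) and 414 at 15 h (22) of PD-005, qseF 14 at 6 h (56) and 40 at 15 h (15) of PD-005, MG1655 30 in batch (52) and 60 at 15 h (38), baeR 92 at 18 h (46), and the interactions 60 for qseF in PD-003 (27) and 0 for phoB in PD-005 (1). These fits held fewer libraries. On fed-batch conditions alone, kdpE had 3 (33), qseC 8 (32), lsrB 3 (1), lsrR 44 (70) and lsrK 16 (57). With the PD-005 wild type as the reference, a group of another run, basS had 788 (525), kdpE 208 (33), qseB 121 (25), qseC 174 (32), lsrB 13 (1), lsrR 111 (70), arcA 602 (45), lsrK 182 (57), luxS 69 (0) and tnaA 32 (2). Without the 8 PD-005 libraries under 1500000 counts, phoB had 19 in batch (29) and 10 at 6 h (42), qseF 20 at 6 h (56), MG1655 82 in batch (52) and the phoB interaction 0 (1). Without the 4 libraries that went against their labels, lsrB had 17 (1) and luxS 30 (0).

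Over all runs replicate numbers showed no clear pairing of the samples. Over 278 pairs of groups the mean correlation of same-numbered deviations had a median of 0.0153 (range -0.601 to 0.528). In 43 pairs every same-numbered correlation was over 0.1, and in 28 the mean was under -0.1. The rule for the former is the stricter, so pairs over 0.1 may be undercounted. In PD-004 the median was 0.0878, with 23 of 55 pairs over 0.1 and 3 under -0.1, so a weak pairing there is not excluded. With the replicate number as a block, phoB had 348 in batch (29) and 342 at 6 h (42) of PD-005, MG1655 152 at 6 h (28), and the interactions 93 for phoB (1) and 19 for qseF (12) in PD-005. Between runs it gave 29 for the wild type (113), 43 for phoB (0), 15 for qseF batch (33), 2 for baeR batch (63) and 1269 for baeR fed-batch (1909). Other counts stayed within 1.5 times under the block.

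With an estimated correlation between genes, the number of gene lists called fell from 56 to 29 of 122 tests in the wild type, from 59 to 19 of 183 for phoB, from 21 to 1 of 183 for qseF, from 26 to 6 of 93 for MG1655 and from 24 to 3 of 60 across strains; none changed direction.

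Each library was left out in turn, except the only library of qseB batch, tnaA batch, tnaA 6 h and baeR 18 h. The ranges for PD-004 and PD-009 do not cover these 4. Ranges were 16 to 20 for phoB batch, 6 to 13 at 6 h and 37 to 171 at 21 h of PD-003; 539 to 908 for the wild type at 21 h and 213 to 432 at 15 h; 11 to 37 for qseF at 6 h and 22 to 106 at 21 h of PD-003 and 5 to 14 in PD-005 batch; 14 to 20 for phoB in batch, 15 to 391 at 6 h and 14 to 17 at 15 h of PD-005; and 18 to 43 for MG1655 in batch and 27 to 58 at 15 h. For the interactions the ranges were 7 to 82 for phoB and 5 to 87 for qseF in PD-003, and 0 to 207 for phoB, 6 to 13 for qseF and 2 to 3 for MG1655 in PD-005. Strain-specific counts ranged from 14 to 37 for kdpE, 15 to 37 for qseC, 1 to 17 for lsrB, 22 to 64 for lsrK, 0 to 14 for luxS, 1 to 2 for tnaA and 100 to 161 for baeR in PD-009. For baeR the ranges were 739 to 925 at 12 h of PD-009 and 28 to 63 at 18 h. Between runs they were 0 to 558 for the wild type, 0 to 304 for phoB, 10 to 32 for qseF batch, 0 to 28 for qseF at 6 h and 22 to 74 for baeR batch. The libraries behind the moved counts are named with each comparison.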

Other observations

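Of the tests in this part, the exchange, the mixture and the regroupings were chosen before their results were seen, and the spread of reads, the wrong rpoS label, all 3 baeR tests and the regroupings without the deleted gene only after. The fixed gene lists held further changes across strains between fed-batch and batch at 6 h (15 blocks). Osmotic stress genes fell in 8 of 10 cases and rose in 2, the same counts adjusted over the list alone; proW and proV of the proline and glycine betaine transporter fell by 4.41 ± 0.13 and 4.40 ± 0.14 on the log2 scale, proX by 3.53 ± 0.16 and the symporter gene proP by 2.99 ± 0.05 (camera adjusted p = 6.3e-06; adjusted p = 0.15 with an estimated correlation). Curli and fimbriae genes rose in 8 of 16 cases and fell in 3, with the same counts adjusted over the list alone. The curli assembly and secretion genes csgF (4.54 ± 0.16), csgE (4.33 ± 0.12) and csgG (4.07 ± 0.12) and the regulator gene csgD (3.95 ± 0.11) were among them (adjusted p = 0.014; adjusted p = 0.42 with an estimated correlation). Tryptophan use and indole genes rose in 5 of 6 cases (5 adjusted over the list alone), led by tnaA (7.17 ± 0.20) and the tryptophan permease gene tnaB (5.91 ± 0.23; adjusted p = 0.042; adjusted p = 0.2 with an estimated correlation). Among these 5 were mdtE and mdtF, which are also on the acid resistance list. The mannose transporter genes manX, manY and manZ of the glucose PTS list rose by 2.43 ± 0.08, 2.43 ± 0.08 and 2.38 ± 0.08, and 5 of the 7 genes of that list rose (5 adjusted over the list alone; adjusted p = 0.0092; adjusted p = 0.45 with an estimated correlation). The nitrate reductase gene narG fell by 3.35 ± 0.09 and aspA, aspartase, rose by 2.92 ± 0.07, while their anaerobic list as a whole was not called (adjusted p = 0.94).

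Between 15 h and 6 h of fed-batch, ATP synthase genes rose in 9 of 9 cases, atpB by 0.43 ± 0.07 and atpA by 0.36 ± 0.06, and glycolysis genes fell in 11 of 13 cases, pykF by 0.48 ± 0.07, with the same counts adjusted over each list alone (adjusted p = 0.034 and 0.0053; adjusted p = 0.54 and 0.51 with an estimated correlation). Microaerobic oxidase genes fell in 9 of 11 cases (10 adjusted over the list alone), led by the hydrogenase 1 genes hyaB (-1.07 ± 0.10) and hyaA (-1.02 ± 0.13; adjusted p = 0.0053; adjusted p = 0.2 with an estimated correlation). Anaerobic and fermentation genes fell in 15 of 24 cases and rose in 1 (16 lower and 2 higher adjusted over the list alone), with the fumarate reductase gene frdA at -0.49 ± 0.04 (adjusted p = 5.5e-05; adjusted p = 0.28 with an estimated correlation). The tryptophan list had a median of 0.15, a mean of -0.67 and a downward test direction, and was not called (adjusted p = 0.38). Its members mdtE and mdtF, which are also on the acid resistance list, were at -2.73 and -2.47. In contrast tnaB rose by 0.68, and tnaA was at 0.18 without passing.

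The deleted genes were out of place in the libraries labelled lsrK and luxS fed-batch 6 h replicate 2. No biological explanation was tested for this pattern or the 2 after it, since the design gives none. Over 118 genes that differed between the strains in batch and at 15 h, the median difference between these libraries, signed by the strain difference, was -1.44 (quartiles -2.19 and -0.76), with the sign turned in 113 genes, while for replicate 1 it was 1.34 with 111 genes keeping the sign. A large spread of reads between the 2 libraries is excluded by 0 lsrK counts in that labelled luxS. From replicate 1, 103 were expected there. A small spread stays open, since the library labelled lsrK held reads of both genes. It had 53.4 CPM of lsrK and 6 luxS counts. The latter are 4.16 CPM, against a median of 458 CPM in the libraries outside the luxS label. flu was at 938 CPM in the library labelled luxS, within the 845 to 1709 CPM of the other lsrK libraries, and at 141 CPM in that labelled lsrK, just under the 148 to 168 CPM of the other luxS libraries. An exchange of the 2 libraries is therefore a candidate explanation for this pair, and it leaves the 14.6 CPM of lsrK in the library labelled lsrK replicate 1 unexplained.

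The library labelled lsrB fed-batch 6 h replicate 1 held lsrB reads. An rpoS library under a wrong label is excluded by 2694 CPM of rpoS, against at most 658 CPM in the rpoS libraries at 6 h and at least 5526 CPM in lsrB replicates 2 and 3. Over 360 rpoS-specific genes the library lay at a median position of 0.564 (quartiles 0.505 and 0.613) between lsrB replicates (0) and rpoS libraries (1), and the rpoS reads gave 0.586. The lsrB reads gave 0.482, just outside those quartiles, so a mixture with an rpoS library may be the cause but stays open.

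A run of 31 neighbouring genes had 3 counts over the 9 baeR libraries. Low depth is excluded by 13829 expected counts, and an absence from the BW25113 background or from the counting by the 30 genes with a median above 1 CPM in the 106 other BW25113 libraries; the lowest total of the run in any other library was 363 counts. The 17 measured genes on both sides had a median ratio of 1.23 to the other strains. They were unlike each other: fimA had a median of 6487 CPM against 857 CPM in the other strains, and uxuA 40.5 CPM against 79.0 CPM. The ratio thus shows reads on both sides, not unchanged levels. A deletion of this stretch in the baeR strain used is a candidate explanation; fimB and fimE lie in it, fimA next to it, and the effect of baeR itself was not separated from it.

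Libraries were also regrouped at random to see whether chance gives as many strain-specific genes, with 100 regroupings each, the real one included. For basS, qseB and qseC 1 of them, the real one, gave as many (525, 25 and 32 genes, with 0 in every other). For kdpE 1 did (33, highest other 1), for rpoS 1 (1676, highest other 731), for arcA 1 (45, highest other 14) and for lsrK 1 (57, highest other 25). For lsrR 2 did (70, highest other 154) and for lsrB 11 (1, highest other 919). The regroupings put libraries of different strains into 1 group, so strain differences entered the spread within groups. The median of the other regroupings was 0 for each strain. A low share therefore shows only that libraries of a strain resembled each other. It does not exclude chance for the genes of a given strain. For tnaA 2 gave as many (2, highest other 3). 1 of its genes is the deleted tnaA itself, which the real grouping must call. Not counting the deleted gene, 4 of 100 gave as many (1, highest other 3), so chance is not excluded for lrhA. For the other strains this left the number of regroupings as it was. For luxS the count of 100 was fixed by the 0 genes of the real grouping (highest other 3), so that test decides nothing. Across strains 1 of 100 gave as many, for 6 h (3128, highest other 1630) and 15 h (1894, highest other 783). For qseF at 6 h of PD-005 there are 10 splits, too few for a share under 0.05; the real one gave 56 genes and the highest other 1.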
